A study of Mus musculus with 6 samples.

How the data were processed

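Gene expression was measured by RNA sequencing of messenger RNA (libraries made with an Illumina TruSeq kit from total RNA, per the labels' protocols) in 6 cultures of mouse embryonic fibroblasts, 3 wild-type and 3 heterozygous for Lztr1. Groups were taken from the genotype given for each sample, and cultures are named by the number in their titles. The authors deposited 1 table per library, and per the file headers each holds RSEM gene-level estimates. RSEM version 1.3.1, DESeq2 and the genome build mm10 are named in the submitters' processing notes. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited expected counts are RSEM's estimates of reads per gene, which share reads that match several genes between them, and 7.53% to 8.80% of the values in a library were not whole. The deposited TPM values are RSEM's abundances, scaled for gene length and library size, and were used for 1 alternative test and for levels of Lztr1. The deposited FPKM values were examined and not used for any test. Effective gene lengths in the deposited tables were used as an offset in 1 alternative.

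Each table held 51826 genes, identified by versioned Ensembl numbers. Symbols and mm10 coordinates were taken from the GENCODE annotation of the same assembly by matching the identifiers, which gave a symbol for 51633 genes and none for 193. The identifier was the same to the version for 47648 genes. Genes that share reads with near-identical copies, and genes that overlap others on either strand, were not resolved further, so their values are uncertain.

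Expected counts were rounded to whole numbers. Genes with low counts were removed with filterByExpr, which left 14652 genes. Library composition was scaled with TMM factors, and the genotypes were compared over the 6 libraries with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 without covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are heterozygous over wild-type, SE values are those of the fitted log2 difference, and CPM values are counts scaled by library total and TMM factor. The confidence interval of the Lztr1 ratio is at 95% and comes from the edgeR fit. The CPM values of Lztr1 were also compared with an exact two-sided permutation test.

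Before the data were examined, 32 gene lists were fixed. They cover LZTR1 ligase partners and RAS-family substrates, RAS-MAPK components, ERK output, immediate-early, DNA replication, mitotic, p53, senescence, matrix, contractile, YAP-TEAD, TGF-beta, ESCRT, lysosome, interferon, NF-kB, cholesterol, glycolysis and hypoxia, unfolded protein and ATF4, NRF2, angiogenic and Hox genes, and the genes next to Lztr1. The other lists are markers of skeletal muscle, endothelium, macrophages and blood, erythroid cells, epithelium, neural and Schwann cells, cartilage and bone, fat, and mesothelium and kidney stroma. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares the members of a list with all other genes. It was repeated with the correlation estimated per list, and fry was run as a test of the list's own genes. With an estimated correlation camera also uses the few residual degrees of freedom of the libraries, where the preset form uses the number of genes. A higher p with the estimate can therefore come from this change as well as from correlation between members. The estimated form was not run on the simulated lists, so its power is not known. A list that does not pass by it may have no shift or may be missed. Members were also adjusted over the list alone. Vps28 of the ESCRT list had no match among the identifiers and was not analysed here.

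Genes were named by a rule fixed before the data were examined. It names Lztr1 always, and the 12 largest changes in each direction among genes that pass the threshold, have separated groups and reach 1 TPM in the higher group, leaving out predicted genes, pseudogenes and genes on the sex chromosomes. Besides Lztr1 no gene passed, so the rule's fallback applied, and the 5 smallest unadjusted p in each direction are given as not past the threshold. Within a list, up to 4 members past the threshold over all genes or over the list alone are named, or otherwise up to 3 by unadjusted p as values. Sex-linked genes were examined per library.

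Library totals ran from 11025286 to 21885101 expected counts. The biological coefficient of variation was 11.3% and the median SE of a log2 difference was 0.11. Counting floors of 3 counts cover counting error only. The steps were tested on simulated counts for 14652 genes in 3 against 3 libraries. The edgeR test recovered 44.8% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 93.9% of those changed 4-fold, with 14 false calls. DESeq2 1.42.0 recovered 49.3%, 77.6% and 93.9%, with 39 false calls. Changes were planted in 67, 67 and 66 genes at these sizes. Where so many genes change, the adjusted threshold is easier to reach than where few do. These shares therefore do not give the power of the real comparison, where 1 gene was called. Lztr1, when its simulated level was reduced as in a single-copy loss, was called in 20 of 20 simulations. A list shifted by 0.3 on the log2 scale was recovered with 0 other lists called, and 20 simulations without any effect called 1 list in all. The simulated genes were independent of each other, so this says nothing about lists whose members vary together. Pairs of libraries were compared by a chi-square over degrees of freedom, with a lowest value of 3.98, so no library appeared to be a copy of another.

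Alternatives fixed before the data were examined were other scaling factors (RLE, upper quartile, library totals), no or a stricter low-count filter (1 CPM in 3 libraries and a mean of 2 CPM), DESeq2, limma-voom, limma on log2(TPM + 1), effective lengths as an offset, the registration block as a term, the first block alone, removal of genes on the sex chromosomes, a term for Y-linked expression, an adjusted p of 0.1, and leaving out each culture. Added after the data were examined were removal of each library's trend on transcript length and GC content (natural splines with 4 degrees of freedom, 99.9% of tested genes having both values), robust dispersion shrinkage, the run of culture numbers as a term, combinations of these or of DESeq2 with culture 16 left out, an estimated correlation with each culture left out, the list of genes next to Lztr1 without Tuba8, which lies on chromosome 6, and a set test of 18 limb patterning genes. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, permutation tests were run in R, and figures were drawn with matplotlib 3.10.9.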

Results

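Messenger RNA was profiled in mouse embryonic fibroblasts (MEFs), primary connective-tissue cells grown from embryos, on a C57BL/6 background. The groups were 3 wild-type cultures, numbered 10, 12 and 16, and 3 cultures heterozygous for Lztr1, numbered 11, 15 and 18. Lztr1 encodes a substrate adaptor of the CUL3 ubiquitin ligase that acts on RAS-family proteins. The comparison addresses which transcripts differ between heterozygous and wild-type cultures. The structure of the mutant allele is not given in the sources used here, so it is unknown which reads from the mutant copy could still be counted in the level of Lztr1. Library totals of gene-level expected counts were 14030349 in wild-type culture 10, 11100487 in 12 and 11025286 in 16. They were 14445884 in heterozygous culture 15, 11028854 in 18 and 21885101 in 11. A count of 3 equalled 0.137 CPM (counts scaled to library size) in the deepest library and 0.272 CPM in the shallowest. Cultures 10, 12, 15 and 18 were registered in a first block and cultures 11 and 16 in a later one, and the culture numbers form the runs 10 to 12 and 15 to 18, so values are also given within these sets. The runs were noticed after the data were examined, and neither the runs nor the blocks are named as batches in the labels. Nothing in the labels says that cultures came from separate embryos or litters, so p-values measure the spread between these cultures, which may be partly technical. Every culture carries the same passage range in its label.

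Lztr1 fell to 49.7% of its wild-type level in the heterozygous cultures. The gene (ENSMUSG00000022761.10, a protein-coding gene on the plus strand of chromosome 16 from 17508688 to 17526333 in mm10) measured 90.4 ± 6.21 CPM in wild-type and 44.9 ± 1.01 CPM in heterozygous cultures (SD, n = 3 each). The 95% confidence interval of the ratio was 44.7% to 55.3%. On the log2 scale the difference was -1.01 (SE 0.066), at an adjusted p of 0.00457 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The libraries stood at 93.9, 94.1 and 83.2 CPM in wild-type cultures 10, 12 and 16, and at 45.9, 45.1 and 43.8 CPM in heterozygous cultures 11, 15 and 18, so Lztr1 matched the genotype label in all 6. Deposited TPM values averaged 61.4 ± 4.08 in wild-type and 32.1 ± 3.80 in heterozygous cultures. Within cultures 10 to 12 the log2 difference was -1.03 and within 15 to 18 it was -0.90. Within the first registered block it was -1.08 and within the later pair, with 1 culture per genotype, -0.86. The exact two-sided permutation test on the CPM values gave p = 0.1, the smallest that 3 against 3 can give. The adjusted p of Lztr1 by edgeR was above 0.05 when any 1 culture other than wild-type 16 was left out, reaching 0.0759 without heterozygous 18, while the log2 difference stayed between -1.06 and -0.97 in these fits.

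**Figure D1:**
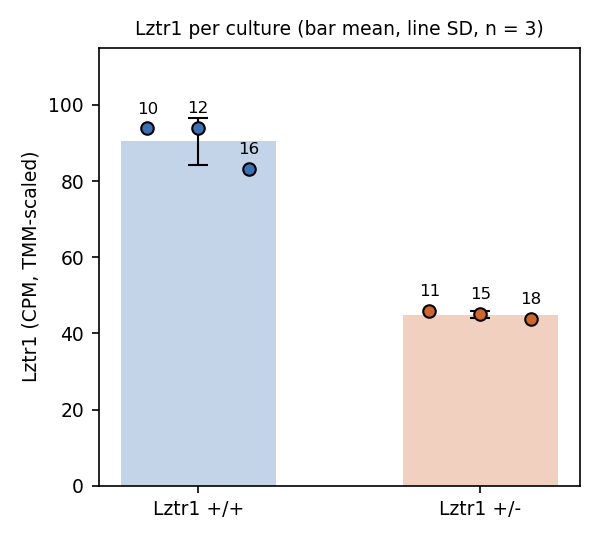
Lztr1 in CPM (TMM-scaled) for each culture, with culture numbers beside the points; bars give the mean of 3 cultures and lines the SD. The wild-type cultures lie between 83.2 and 94.1 CPM and the heterozygous cultures between 43.8 and 45.9 CPM.

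Beyond Lztr1, no transcript passed the gene-wide test in the 6 libraries, though 80 genes, Lztr1 included, had an estimated difference of 2-fold or more. The nearest was Hipk2, a kinase that acts on transcriptional regulators including p53, at 34.8 ± 0.982 CPM in wild-type and 55.6 ± 3.68 CPM in heterozygous cultures (SD, n = 3 each), a log2 difference of 0.68 (SE 0.070) with an adjusted p of 0.0742 by edgeR. The other transcripts with the smallest unadjusted p among those higher in heterozygous cultures all had an adjusted p of 0.305. They were the mitochondrial transcript mt-Co2 (log2 difference 0.84, SE 0.11), the endocytic adaptor Ston1 (0.38, SE 0.054), the insulin receptor adaptor Irs1 (0.35, SE 0.055) and Cbl, a ubiquitin ligase for receptor tyrosine kinases (0.33, SE 0.057). Counts of mt-Co2 can be shared with near-identical nuclear copies of the mitochondrial genome, so its value is uncertain. On the lower side, also at an adjusted p of 0.305, were the matrix protein gene Thbs4 (-0.89, SE 0.13), the chondroitin sulfate enzyme gene Csgalnact1 (-0.82, SE 0.13), the retinoic acid carrier gene Crabp2 (-0.68, SE 0.11), the homeobox gene Hoxd13 (-0.58, SE 0.094) and the calcineurin-regulated transcription factor gene Nfatc4 (-0.50, SE 0.079). For each of these 10 genes all heterozygous cultures lay on one side of all wild-type cultures, as the rule for naming them required.

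That rule fixes the sign of each difference within any set of the cultures, so the values within the runs show size alone. Hipk2 differed by 0.62 within cultures 10 to 12 and by 0.74 within 15 to 18. For mt-Co2 the values were 0.91 and 0.69, for Ston1 0.32 and 0.42, for Irs1 0.30 and 0.37, and for Cbl 0.30 and 0.32. Thbs4 differed by -1.10 and -0.59, Csgalnact1 by -0.81 and -0.73, Nfatc4 by -0.42 and -0.46, Hoxd13 by -0.46 and -0.58, and Crabp2 by -0.61 and -0.58.

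Of 14652 tested genes, 1790 had an unadjusted p under 0.05, 815 higher and 975 lower in heterozygous cultures, where 733 would be expected by chance. The balance of directions moved with the settings, with 635 higher and 1235 lower when scaled by library totals, 555 and 950 with the length and GC trend removed, and 1222 and 1096 without a low-count filter. The groups did not overlap in 2597 genes, or 17.7%, against a mean of 10% over the possible splits of 3 against 3. Genes vary together across the 6 libraries, so a single split can exceed these chance values without an effect of genotype. Between the culture number runs, with genotype in the model, edgeR gave 2001 genes at an unadjusted p under 0.05. DESeq2 called 117 genes on the same counts, 63 higher and 54 lower. Without wild-type culture 16 the edgeR test called 896 genes, 557 higher and 339 lower, and all 10 genes named above then passed, with adjusted p from 0.00664 for Thbs4 to 0.0190 for Cbl. The wild-type cultures left in that fit, 10 and 12, share a run and a block, so genotype is partly confounded with both. With the culture number run as a term as well, edgeR called 291 genes. The 10 genes were picked on libraries that this fit shares, so their passing is not independent support. Without any 1 of the other cultures edgeR called 0 genes, with 909 to 1862 genes at an unadjusted p under 0.05. With the first registered block alone (cultures 10 and 12 against 15 and 18), where genotype and run coincide, it called 1450 genes, 803 higher and 647 lower.

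Wild-type culture 16 lay apart from the other wild-type cultures. The root mean square log2 difference over genes was 0.377 between wild-type cultures 10 and 12, 0.466 between 16 and 10, and 0.498 between 16 and 12, while 16 differed from heterozygous cultures 15, 11 and 18 by 0.421, 0.430 and 0.515, the last being the largest of the 15 pairs. Heterozygous culture 11 and wild-type culture 10 differed by 0.366. A chi-square over degrees of freedom on the counts ordered the pairs otherwise. It was 3.98 between cultures 10 and 12, and 11.7 to 14.4 between either of them and the other cultures. Among cultures 11, 15, 16 and 18 it was 4.32 to 8.43. The first principal component held 29.2% of the variance and the second 29.0%, and the second had cultures 10, 12 and 11 on one side and 15, 18 and 16 on the other. It also followed genotype within the runs. Wild-type cultures 10 and 12 scored 26.5 and 17.3 against 7.80 in heterozygous 11, and wild-type 16 scored -10.1 against -20.1 and -21.5 in heterozygous 15 and 18. Xist was high in wild-type cultures 10 and 16 and heterozygous culture 11. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were high in wild-type culture 12 and heterozygous cultures 15 and 18. Both groups therefore held female and male cultures, but in unequal numbers, so sex is partly confounded with genotype. With a term for Y-linked expression 1449 genes had an unadjusted p under 0.05 in edgeR, against 1790 without it. With that term 15 lists passed camera at the preset correlation, against 11 without it. The distances above include sex-linked genes, which add to those between a female and a male culture.

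**Figure D2:**
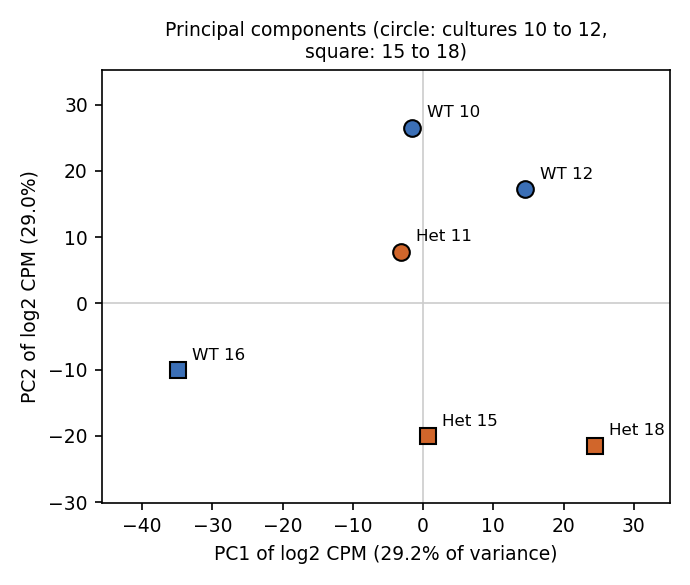
Scores of the 6 libraries on the principal components of log2 CPM; blue marks wild-type and orange heterozygous cultures, circles mark cultures 10 to 12 and squares 15 to 18. The second component (29.0% of variance) separates the runs of culture numbers, and within each run the wild-type cultures score higher on it than the heterozygous. Wild-type culture 16 is alone at the low end of the first (29.2%).

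Gene groups fixed in advance were compared between the genotypes with camera at a preset inter-gene correlation, and 11 of 32 passed, 7 higher and 4 lower in heterozygous cultures. With an estimated correlation 0 of them passed in camera, where 2 had an unadjusted p under 0.05 (contractile and Hox genes), and 0 of the 32 passed when the estimate was combined with leaving out any 1 culture. The directional test of fry passed 0 groups, with 3 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0529. No member of any group passed edgeR's test over all 14652 genes. Without wild-type culture 16 edgeR called 7 contractile, 5 p53 and 1 NF-kB genes as higher, and 5 Hox, 3 unfolded protein and 2 cholesterol genes and 1 skeletal muscle marker as lower. The wild-type cultures left in that fit share a run and a block. These counts, and those given for it below, therefore mix genotype with run and block. The contractile and Hox groups passed camera with the preset correlation in all 6 fits that left out a culture, and in none of these with an estimated correlation (lowest adjusted p = 0.359). With the culture number run as a term 5 groups passed, namely contractile, Hox, YAP-TEAD and neural genes at an adjusted p of 0.00222 each and lysosome genes (0.0277), and the other 7 of the 11 calls were lost. With that term and an estimated correlation 0 groups passed, with a lowest adjusted p of 0.715 (Hox genes).

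Contractile and myofibroblast genes, which encode smooth-muscle actin and its partners, were higher in heterozygous cultures as a group at the preset correlation. Of 14 tested genes 12 had a higher mean, with a median log2 difference of 0.21 (camera adjusted p = 0.000787). The adjusted p was 0.513 with an estimated correlation. Adjusted over the list alone 6 genes rose and 0 fell, against 0 over all genes in edgeR and 3 in DESeq2. They included Lmod1, which nucleates actin filaments (0.46, SE 0.083), the actin-binding genes Cald1 (0.28, SE 0.062) and Cnn1 (0.35, SE 0.10), and Acta2, encoding smooth-muscle actin (0.24, SE 0.066, from 4963 to 5848 CPM). The mean over the list lay 0.20 ± 0.043 above the wild-type mean in heterozygous cultures, against a wild-type SD of 0.045 (n = 3 each), and the difference was 0.19 within cultures 10 to 12, 0.17 within 15 to 18, 0.23 in the first block and 0.13 in the later pair.

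Hox genes, the homeobox genes that mark position along the body and limb axes, were lower as a group at the preset correlation, though not in every member. The median log2 difference over 37 tested genes was -0.21, with 24 lower and 13 higher (camera adjusted p = 0.00267). The adjusted p was 0.512 with an estimated correlation. That estimate was 0.0041, below the preset 0.01, so the rise in p does not come from correlation between the members. Adjusted over the list alone 8 fell and 0 rose, against 0 over all genes in edgeR and 2 in DESeq2. Those with the smallest p were Hoxd13, Hoxa10 (-0.70, SE 0.14), Hoxa13 (-0.74, SE 0.15) and Hoxd11 (-0.59, SE 0.12). The mean over the list was -0.25 ± 0.097 in heterozygous cultures relative to the wild-type mean, against a wild-type SD of 0.063, and the difference was -0.40 within cultures 10 to 12, -0.13 within 15 to 18, -0.23 in the first block and -0.30 in the later pair.

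**Figure D3:**
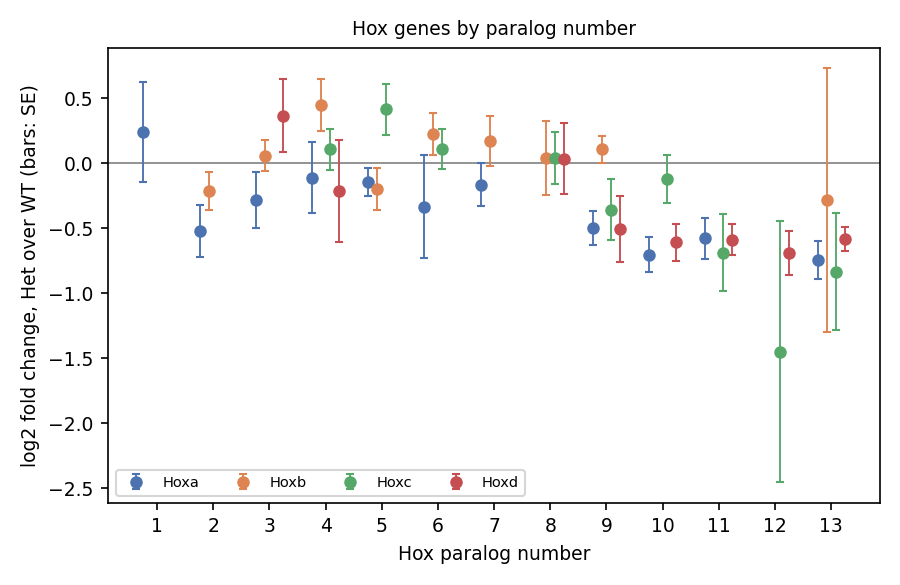
Log2 difference, heterozygous over wild-type, of each tested Hox gene by paralog number, coloured by cluster; bars give the SE of the fit (n = 3 each). Of the genes with paralog numbers 9 to 13, 15 of 16 are lower in heterozygous cultures, against 9 of 21 with numbers 1 to 8.

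Genes downstream of ERK, the kinase at the end of the RAS pathway, were higher in heterozygous cultures as a group, and so was wild-type culture 16. Of 18 ERK output and feedback genes 16 had a higher mean, with a median of 0.19 (camera adjusted p = 0.0171). The adjusted p was 0.856 with an estimated correlation. None passed in edgeR adjusted over the list alone, 2 had an unadjusted p under 0.05 and DESeq2 called 0. The phosphatase gene Dusp4 differed by 0.62 (SE 0.19), the receptor gene Epha2 by 0.59 (SE 0.25) and the cyclin gene Ccnd1 by 0.23 (SE 0.10). Relative to the wild-type mean the list stood at 0.24 ± 0.050 in heterozygous cultures (SD, n = 3), and at -0.13, -0.21 and 0.34 in wild-type cultures 10, 12 and 16. The difference was therefore 0.38 within cultures 10 to 12 and -0.08 within 15 to 18, with 0.43 in the first block and -0.13 in the later pair, and the group did not hold its direction within these sets. With the culture number run as a term its adjusted p was 0.0639, without wild-type culture 10 it was 0.114 and without 12 it was 0.257. Without wild-type culture 16 it was 3.51e-06 (adjusted p = 0.359 with an estimated correlation), and edgeR called 10 of the 18 genes as higher. Markers of erythroid cells also had wild-type culture 16 with the heterozygous cultures, at -0.35, -0.65 and 1.01 in wild-type cultures 10, 12 and 16 and at 0.38, 0.90 and 0.76 in heterozygous cultures 11, 15 and 18. Other marker lists in culture 16 went both ways, with neural markers at -0.49, skeletal muscle at -0.36 and epithelial at 0.33. A link between erythroid markers and ERK output genes was not tested.

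Targets of YAP and TEAD, transcription regulators that respond to cell shape and density, were also higher as a group, with wild-type culture 16 at the level of the heterozygous cultures. Of 22 genes 17 were higher, with a median of 0.21 (camera adjusted p = 0.00267). The adjusted p was 0.856 with an estimated correlation. Adjusted over the list alone 0 passed in edgeR, with 6 at an unadjusted p under 0.05 and 1 called by DESeq2. F3, encoding tissue factor, differed by 0.67 (SE 0.21), Amotl2 by 0.38 (SE 0.12) and Myof by 0.32 (SE 0.087). Wild-type culture 16 stood at 0.24, beside a heterozygous mean of 0.24 ± 0.047 and wild-type cultures 10 and 12 at -0.13 and -0.11. The difference was 0.41 within cultures 10 to 12 and -0.03 within 15 to 18, with 0.34 in the first block and 0.05 in the later pair. With the culture number run as a term the adjusted p was 0.00222 (adjusted p = 0.853 with an estimated correlation), and without heterozygous culture 11 it was 0.0540. Without wild-type culture 16 it was 3.51e-06 (adjusted p = 0.359 with an estimated correlation), where edgeR called 12 of the 22 genes as higher. Erythroid markers, at 1.01 in culture 16 and -0.35 and -0.65 in 10 and 12, had culture 16 on the same side. A link between these markers and the YAP-TEAD list was not tested.

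Among the remaining groups that were higher, DNA replication genes had 17 of 23 members above the wild-type mean and a median of 0.07 (camera adjusted p = 0.0171, and adjusted p = 0.856 with an estimated correlation). Ccne2 differed by 0.26 (SE 0.076) and Mcm2 by 0.15 (SE 0.051), and the list mean differed by 0.02 within cultures 10 to 12 and 0.09 within 15 to 18. For p53 target genes 15 of 17 were higher with a median of 0.15 (camera adjusted p = 0.0248, and adjusted p = 0.856 with an estimated correlation). Ccng1 differed by 0.31 (SE 0.11) and Eda2r by 0.30 (SE 0.092), and the list mean by 0.40 and -0.13 within the runs. NF-kB and inflammatory genes had 16 of 18 higher and a median of 0.28 (camera adjusted p = 0.0278, and adjusted p = 0.856 with an estimated correlation). The growth factor gene Csf1 differed by 0.43 (SE 0.18) and the complement gene C3 by 0.72 (SE 0.38), and the list mean by 0.22 and 0.07 within the runs. In the first block and the later pair the list means differed by 0.13 and -0.02 for DNA replication, 0.21 and 0.06 for p53 targets and 0.56 and -0.27 for NF-kB genes. The DNA replication call was lost without wild-type culture 12 (camera adjusted p = 0.111) or heterozygous 15 (0.183). The p53 call was lost without wild-type 10 (0.208) or 12 (0.0982) or heterozygous 11 (0.239), and the NF-kB call without wild-type 10 (0.128) or 12 (0.251) or heterozygous 15 (0.135). With the culture number run as a term the adjusted p was 0.117 for DNA replication, 0.0639 for p53 and 0.0569 for NF-kB genes. Wild-type culture 16 stood at 0.22 for p53 and 0.33 for NF-kB genes, above wild-type 10 and 12, beside its 1.01 for erythroid markers. Macrophage and blood markers stood at -0.06, -0.18 and 0.24 in wild-type cultures 10, 12 and 16, and at -0.47, 0.34 and 0.41 in heterozygous 11, 15 and 18. No link of erythroid or macrophage markers to the p53 or NF-kB genes was tested. Adjusted over the list alone 0 genes of these 3 groups passed in edgeR, with 5, 5 and 1 at an unadjusted p under 0.05, and DESeq2 called 0.

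Cholesterol synthesis genes were lower in 20 of 24 cases, with a median of -0.09 (camera adjusted p = 0.0288, and adjusted p = 0.856 with an estimated correlation). Mvd differed by -0.31 (SE 0.10) and Fdps by -0.21 (SE 0.081). Genes of the unfolded protein and ATF4 responses were lower in 16 of 22 cases, with a median of -0.10 (camera adjusted p = 0.0397, and adjusted p = 0.856 with an estimated correlation). Trib3 differed by -0.58 (SE 0.16), Nupr1 by -0.25 (SE 0.079) and Ddit4 by -0.19 (SE 0.072). Within cultures 10 to 12 the list means differed by -0.27 and -0.28, and within 15 to 18 by 0.08 and 0.07, so neither group held its direction in both runs. In the first block both differed by -0.12, and in the later pair by -0.07 and -0.09. The calls were lost without wild-type culture 10 (camera adjusted p = 0.128 and 0.157), wild-type 12 (0.365 and 0.251) or heterozygous 11 (0.509 each), and with the culture number run as a term (0.0549 each). With the length and GC trend removed the unfolded protein call was also lost (0.168). Wild-type culture 16 stood at -0.13 in both lists, below wild-type 10 and 12, beside its 1.01 for erythroid markers. A link between erythroid markers and these lists was not tested. In each group 0 genes passed in edgeR adjusted over the list alone, 5 had an unadjusted p under 0.05, and DESeq2 called 0.

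Markers of 2 other cell types also passed. Skeletal muscle markers were lower in 16 of 17 cases, with a median of -0.25 (camera adjusted p = 0.0145, and adjusted p = 0.856 with an estimated correlation). The myoblast fusion gene Mymk differed by -0.35 (SE 0.15) and the troponin gene Tnnt3 by -0.43 (SE 0.19). The list stood at 0.24 and 0.12 in wild-type cultures 10 and 12 and at -0.36 in 16, with differences of -0.19 and -0.03 within the runs, -0.56 in the first block and 0.34 in the later pair. The call was lost without wild-type culture 10 (camera adjusted p = 0.143) or 12 (0.0982) or heterozygous 15 (0.246), and with the culture number run as a term (0.0727). Neural and Schwann cell markers were higher in 13 of 15 cases, with a median of 0.24 (camera adjusted p = 0.0456, and adjusted p = 0.856 with an estimated correlation). Tubb3 differed by 0.47 (SE 0.18) and Dcx by 0.73 (SE 0.43). The neural list stood at -0.49 in wild-type culture 16 and at 0.37 and 0.12 in 10 and 12, against a heterozygous mean of 0.31 ± 0.24, with differences of 0.20 and 0.73 within the runs, -0.0072 in the first block and 0.93 in the later pair. The neural list had a camera adjusted p of 0.601 without wild-type culture 16, 0.378 without wild-type 12, 0.344 without heterozygous 11 and 0.0755 without heterozygous 18. Adjusted over the list alone 0 genes of either list passed in edgeR, with 1 and 2 at an unadjusted p under 0.05, and DESeq2 called 0.

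**Figure D4:**
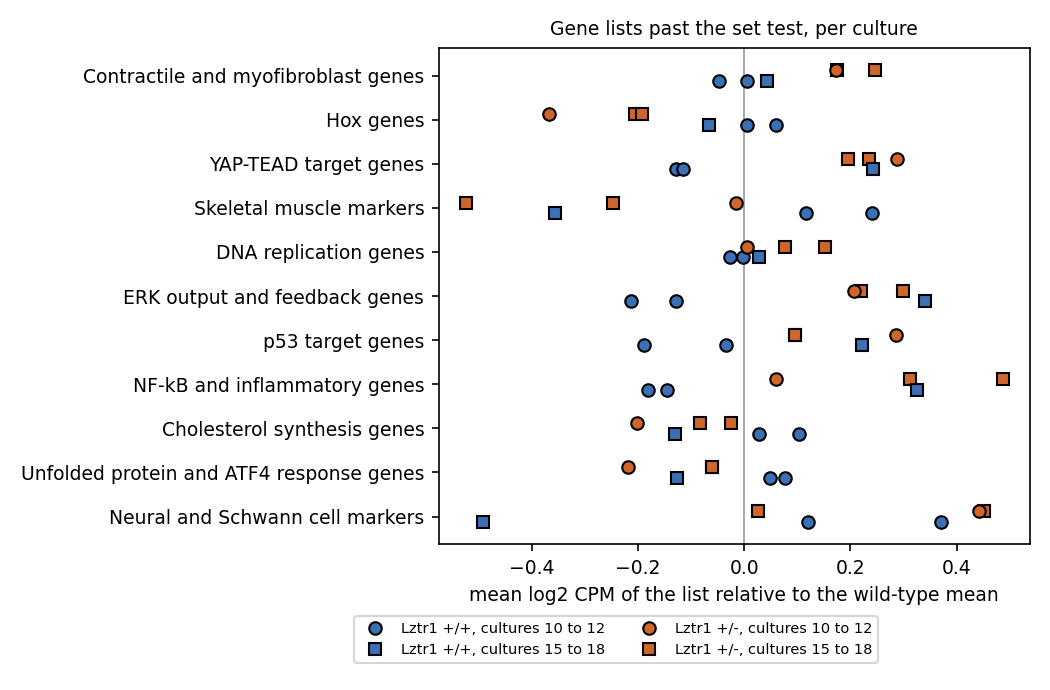
Mean log2 CPM over each gene list that passed camera with the preset correlation, per culture, relative to the wild-type mean; blue marks wild-type and orange heterozygous cultures, circles mark cultures 10 to 12 and squares 15 to 18. Contractile genes (heterozygous mean 0.20) and Hox genes (-0.25) keep the groups apart, while wild-type culture 16 lies at 0.34 for ERK output genes, above every heterozygous culture.

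Genes of the RAS proteins and ligase partners themselves did not pass as a group. Over 10 LZTR1 partners and RAS-family substrates the median was 0.01 (camera adjusted p = 0.855), with Rras at -0.22 (SE 0.066), Rras2 at 0.37 (SE 0.19) and Chmp1a at -0.09 (SE 0.055). Adjusted over the list alone 0 passed in edgeR, with 1 at an unadjusted p under 0.05 and 0 called by DESeq2. Without wild-type culture 16 edgeR called 1 member of this list as higher. Rras2 ran from 0.21 to 0.66 when 1 culture was left out, and differed by 0.57 within cultures 10 to 12 and -0.04 within 15 to 18. RAS-MAPK pathway components had a median of 0.05 over 22 genes (camera adjusted p = 0.133), and Cbl alone rose adjusted over the list alone (adjusted p = 0.00874), against 0 over all genes in edgeR and 1 in DESeq2. By the mixed test of fry, which asks whether members change in either direction, 4 groups passed, namely Hox genes (adjusted p = 0.00969), RAS-MAPK components (0.01), genes next to Lztr1 (0.0156) and contractile genes (0.0460). The list of genes next to Lztr1 had 15 tested members, of which 14 lie on chromosome 16 and 1, Tuba8, on chromosome 6. Its median was -0.0038 (camera adjusted p = 0.995), or -0.0065 over the 14 genes on chromosome 16 (camera adjusted p = 0.790, and 0.0145 by the mixed test of fry). In the full list 2 fell adjusted over the list alone, Scarf2 (-0.35, SE 0.083) and P2rx6 (-1.26, SE 0.34, at 1.27 CPM in wild-type cultures), against 0 over all genes in edgeR and 1 in DESeq2. Over the 14 genes alone these 2 fell and 1, Med15 (0.17, SE 0.051), rose, a member picked after the values were seen. Within cultures 10 to 12 and 15 to 18 Scarf2 differed by -0.22 and -0.39, and P2rx6 by -0.96 and -1.10.

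A further 3 groups had 1 or 2 members past the test over the list alone. Mitotic genes had a median of 0.05 over 24 genes (camera adjusted p = 0.0539, and 0.0214 without wild-type culture 10, 0.0410 without heterozygous 18, 0.00792 without heterozygous 11 and 0.0465 with the stricter filter). With an estimated correlation the adjusted p was 0.856 on 6 libraries and 0.843, 0.821 and 0.870 without those cultures. Hmmr (0.28, SE 0.059) and Anln (0.32, SE 0.080), which act in spindle assembly and cell division, rose adjusted over the list alone. Angiogenic ligands and receptors had a median of -0.05 and a mean of -0.0043 over 16 genes while camera ranked them as higher (adjusted p = 0.855), and the receptor gene Nrp1 (0.29, SE 0.069) rose adjusted over the list alone. TGF-beta response genes had a median of -0.05 over 16 genes (camera adjusted p = 0.641), and the feedback regulator gene Pmepa1 (-0.30, SE 0.063) fell adjusted over the list alone. In each of these genes the groups did not overlap, so the sign within the runs of culture numbers was fixed, and the sizes within 10 to 12 and 15 to 18 were 0.19 and 0.34 for Hmmr, 0.29 and 0.26 for Anln, 0.38 and 0.21 for Nrp1, and -0.21 and -0.39 for Pmepa1. Over all genes 0 of them passed in edgeR, and DESeq2 called 2 mitotic, 1 angiogenic and 1 TGF-beta gene.

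The remaining 15 groups did not pass camera, and adjusted over the list alone 0 of their genes passed in edgeR, with 0 to 6 genes per group at an unadjusted p under 0.05 and 0 called by DESeq2. Collagen and extracellular matrix genes had a median of -0.12 over 27 genes (adjusted p = 0.0649), with Eln at -0.94 (SE 0.23), Lum at -0.79 (SE 0.27) and Dcn at -0.64 (SE 0.22). Without wild-type culture 16 the matrix list had an adjusted p of 0.000155 (adjusted p = 0.359 with an estimated correlation) and edgeR called 8 members as lower, and it also passed with the block term (0.0127), the Y-linked term (0.0152) and the length and GC trend removed (0.0198). The matrix list had an adjusted p = 0.856 with an estimated correlation on 6 libraries and 0.913 with that trend removed as well. Its mean differed by -0.31 within cultures 10 to 12, 0.10 within 15 to 18, -0.24 in the first block and 0.03 in the later pair. Erythroid markers had a median of 0.61 over 8 genes (adjusted p = 0.0534), with the embryonic globin gene Hbb-y at 1.23 (SE 0.49), and the adjusted p was 0.0351 without heterozygous culture 11 and 0.00158 without wild-type 16 (adjusted p = 0.870 and 0.359 with an estimated correlation). It was also under the threshold on ranks (0.0341), with upper-quartile factors (0.0434), the stricter filter (0.0439), the block term (0.0418), the Y-linked term (0.0244) and the length and GC trend removed (0.0198). The erythroid list had an adjusted p = 0.856 with an estimated correlation on 6 libraries and 0.913 with that trend removed as well. The erythroid list mean differed by 0.89 within cultures 10 to 12, -0.18 within 15 to 18, 1.33 in the first block and -0.62 in the later pair, so its direction did not hold within these sets. Lysosome and autophagy genes stood at a median of -0.06 over 24 genes (adjusted p = 0.0539, and 0.0214 without wild-type culture 10, 0.0242 without heterozygous 15 and 0.0360 without heterozygous 18). With an estimated correlation the adjusted p without these cultures was 0.843, 0.988 and 0.821. They also passed with the culture number term (0.0277), the Y-linked term (0.0106) and on ranks (0.0341), against adjusted p = 0.853 with the culture number term and an estimated correlation and 0.856 with an estimated correlation alone. Camera gave adjusted p of 0.201 for glycolysis and hypoxia genes (median 0.10, 21 genes), 0.209 for NRF2 targets (0.06, 14 genes), and 0.220 for immediate-early genes (0.10, 17 genes) and for senescence and secretory genes (0.22, 14 genes). Immediate-early genes passed without heterozygous culture 18 (0.000999) or wild-type 16 (0.0140) and with the Y-linked term (0.0213), and senescence genes without wild-type 16 (0.0400). With an estimated correlation the adjusted p was 0.821 and 0.786 for immediate-early genes without those cultures, and 0.501 for senescence genes. It gave 0.312 for interferon response genes (0.07, 29 genes), 0.358 for macrophage and blood markers (0.11, 16 genes) and 0.499 for cartilage and bone markers (-0.10, 17 genes). The interferon and macrophage values rested on heterozygous culture 11, which stood at -0.46 and -0.47 relative to the wild-type mean, against 0.37 and 0.34 in heterozygous culture 15 and 0.31 and 0.41 in 18. Without culture 11 camera gave adjusted p of 6.05e-10 and 2.11e-06 with the preset correlation, and adjusted p = 0.602 and 0.794 with an estimated correlation. For endothelial markers it was 0.597 (0.30, 10 genes), for ESCRT and endosomal sorting genes 0.620 (-0.01, 26 genes) and for adipocyte markers 0.725 (-0.02, 6 genes). For mesothelial and kidney stroma markers it was 0.810 (0.0014, 11 genes). Epithelial and keratinocyte markers, at an adjusted p of 0.967 over 12 genes, had a median of 0.08 and a mean of -0.10. Without wild-type culture 16 edgeR called 7 glycolysis and hypoxia genes as higher and 1 as lower, 4 immediate-early genes as higher, 3 senescence genes as higher and 1 as lower, and 3 erythroid and 2 epithelial markers as higher. It then called 1 gene as higher in each of the NRF2, endothelial and ESCRT lists.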

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

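The length and GC trend removal, robust shrinkage, the culture number term, the neighbour list on chromosome 16 alone and the fits that combine another choice with leaving out a culture were chosen after the results were seen; the other alternatives were not. No paired analysis was possible because the groups share no culture number. Lztr1 was lower in heterozygous cultures under every alternative run, by log2 values from -1.08 (first block alone) to -0.92 (effective length offset), and its adjusted p stayed under 0.05 except with limma on log2(TPM + 1) (-0.92, adjusted p = 0.26), with the effective length offset (-0.92, adjusted p = 0.0747) and when a culture other than 16 was left out. Leaving out each culture gave -1.06 to -0.97, with adjusted p from 0.000446 (without wild-type 16) to 0.0759 (without heterozygous 18). The fits without a culture test fewer samples, and the cause of the other changes was not tested.

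The count of called genes was 1 with all scalings, the stricter filter, limma-voom, the block or Y-linked term, no sex chromosomes, trend removal, robust shrinkage and the culture number term. It was 32 without a filter, 117 with DESeq2, 1450 in the first block alone and 2 at an adjusted p of 0.1. It was 0 with limma on TPM and with effective lengths (1693 and 1612 genes at an unadjusted p under 0.05). Leaving out a culture gave 0 to 896, the highest without wild-type 16. Without that culture trend removal gave 690, DESeq2 1051 and the culture number term 291, and DESeq2 with that term on 6 libraries gave 105. Of the 63 higher and 54 lower genes DESeq2 called, 58 and 50 were among those edgeR called without wild-type 16 (520 and 280 of the 8108 genes tested in both). These fits share 5 libraries, so a large overlap would arise whatever its cause and is not independent support. The count of lists, 11, was 0 with an estimated correlation (2 at an unadjusted p under 0.05), 0 when that was combined with trend removal or with the culture number term (1 each at an unadjusted p under 0.05), 0 when combined with leaving out any 1 culture (1 to 3), 0 with directional fry (3), 4 with mixed fry and 5 with the culture number term. It lay between 12 and 15 on ranks, with upper-quartile factors, the stricter filter, the block or Y-linked term or trend removal. Leaving out a culture gave 3 (without wild-type 12) to 14 (without wild-type 16), with 7 without wild-type 10. Over those fits the adjusted p ran from 0.000559 to 0.00315 for contractile and from 9.45e-05 to 0.0184 for Hox genes, while that of ERK output genes ran from 3.51e-06 to 0.257. Another scaling moved the median log2 difference of all genes to -0.03 at most. At 11025286 counts the shallowest library does not resolve genes near 0.272 CPM.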

Other observations

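The tests of the genotype label of culture 16, of the registration block, of Hox paralog numbers, of limb genes as a set and of the culture number runs were chosen only after the results were seen. With genotype kept in the model, 12 of 32 lists differed between cultures 15 to 18 and 10 to 12 in camera at the preset correlation, and 0 with an estimated correlation (lowest adjusted p = 0.545). Of the 9 lists that mark cells other than fibroblasts 5 were among the 12, and endothelial (adjusted p = 0.130), adipocyte (0.169), mesothelial (0.536) and cartilage markers (0.676) were not. Macrophage and blood markers were higher in 15 to 18 for 16 of 16 genes, with a median log2 difference of 0.60 (camera adjusted p = 4.33e-12), erythroid markers had a median of 1.3 (adjusted p = 2.68e-05) and interferon response genes 0.38 (adjusted p = 0.00017), while skeletal muscle markers had a median of -0.42 with 0 of 17 higher (adjusted p = 1.65e-08). Epithelial markers had a median of 0.75 (adjusted p = 0.000828), and neural markers, higher in heterozygous cultures above, had -0.42 with 2 of 15 higher (adjusted p = 0.00463). ERK output genes were higher in 15 to 18 too, with a median of 0.32 (adjusted p = 0.00033). Among single genes edgeR called 7, with 2001 at an unadjusted p under 0.05. These were Hbb-bs (1.57), Ccl7 (1.09), Ccl2 (0.94), Ttr (0.63) and Csf1 (0.52), higher in 15 to 18, and Fras1 (-0.60) and Prss12 (-0.83), lower.

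Limb patterning genes, 18 picked after the Hox values were seen, had a lower mean in heterozygous cultures in 14 cases, with a median of -0.30 (camera unadjusted p = 0.000137 with the preset correlation, and unadjusted p = 0.124 with an estimated correlation). Their mean differed by -0.17 within cultures 10 to 12, -0.28 within 15 to 18, -0.42 in the first block and -0.03 in the later pair. Pitx1 differed between genotypes by -0.73 (SE 0.15), Msx1 by -0.63 (SE 0.16) and Lmx1b by -0.53 (SE 0.17), with -0.26, -0.03 and -0.04 in the later pair, while the genes that were higher were Lhx2 (0.23, SE 0.20), Meis2 (0.19, SE 0.058), En1 (0.07, SE 0.19) and Meis1 (0.0011, SE 0.10). In edgeR 0 of the 18 passed the adjusted threshold, with 9 at an unadjusted p under 0.05 and an adjusted p of 0.313 for Pitx1. Within the mitochondrial genome mt-Co2 stood at 0.84 (SE 0.11) beside mt-Co3 at -0.29 (SE 0.096) and mt-Atp6 at 0.036 (SE 0.19), the latter pair also picked after their values were seen.

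The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 1 gene and the highest other split 7, and 4 of 10 splits called as many as the real one. Among these is the split of cultures 10, 11 and 16 against 12, 15 and 18 (5 genes), which divides the cultures by sex and so is not a regrouping without effect. For lists the real split called 11 and the highest other 14, and 3 of 10 called as many. The split with 7 genes set cultures 10, 11 and 12 against 15, 16 and 18, and in DESeq2 it called 288 genes against 117 for the real one. Both of these splits set cultures 10 and 12 against 15 and 18, and the other splits with 10 and 12 together called 13 and 40 genes. The splits therefore cannot tell a structure along the culture numbers from a difference between cultures 10 and 12 and the rest. With the culture number run as a term edgeR called 1 gene between genotypes and camera 5 lists.

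Hox genes with paralog numbers 9 to 13, which mark posterior and distal positions, differed by a mean of -0.57 ± 0.34 (SD, 16 genes) between genotypes, and those numbered 1 to 8 by 0.0043 ± 0.26 (21 genes). Transcript length and GC composition are argued against as the whole cause, since with that trend removed the contractile list kept a camera adjusted p of 3.7e-05 at the preset correlation and the Hox list 0.0151, with medians of 0.23 and -0.18 against 0.21 and -0.21 before. With an estimated correlation neither list passed, with the trend removed (adjusted p = 0.913 each) or without (0.513 and 0.512). A candidate explanation is that the cultures held fibroblasts from different positions along the body or limb. The split by paralog number was made after the Hox values were seen, so its difference of -0.57 restates the pattern and leaves this open. Within cultures 10 to 12 the mean of paralogs 9 to 13 differed by -0.88 and within 15 to 18 by -0.36. In the later pair that mean stood at -0.82 in heterozygous culture 11 and -0.13 in wild-type 16, relative to the wild-type mean. The limb genes as a set differed there by -0.03, with single genes from -0.52 (Tbx4) to 0.33 (Lhx2). The set was not divided by position along the limb, and the pair holds 1 culture per genotype. That mean therefore cannot speak for or against position. An effect of Lztr1 dose itself stays open too, because position and genotype were not varied separately.

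Wild-type culture 16 lay 27.9% farther from the other wild-type cultures than these lay from each other. A mislabelled genotype is argued against by its Lztr1 level of 83.2 CPM, against at most 45.9 CPM in a heterozygous culture. Length and GC composition of the library are argued against as the main cause, since removing that trend took away 8.98% of the excess distance. Culture 16 did have the strongest trend on transcript length, with a correlation of -0.30 against -0.0085 to 0.13 in the other libraries. The log2 difference between genotypes itself correlated with length (0.15) and GC content (-0.20), so a part in the cause stays open. An additive difference between registration blocks as the whole cause is argued against, because it would shift cultures 16 and 11 alike, and their deviations from the other cultures of their groups correlated over genes at -0.054; as a part of the cause it stays open, since a difference between the culture number runs would set these cultures apart in opposite directions. Litter, passage and culture density were not tested and stay open.

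Between cultures 10 and 12 on one side and 15 and 18 on the other, 1450 genes were called, and 1448 of them could be placed in the remaining libraries on a scale from the wild-type mean (0) to the heterozygous mean (1) of those 4. Heterozygous culture 11 had a median position of 0.66, with 70.7% of genes nearer the heterozygous side, and wild-type culture 16 had 0.76, with 75.6% nearer. Genotype as the whole cause is argued against by the 0.76 of culture 16, and the culture number runs as the whole cause by the 0.66 of culture 11. Each of these rests on 1 library, and both libraries were registered in the later block. A shift shared by that block could place both on the heterozygous side. These genes were chosen on the 4 libraries, so what the remaining libraries share stays open. Over all genes, sex-linked ones included, culture 10 lay 0.366 from heterozygous 11 and 0.377 from wild-type 12. Cultures 10 and 11 were female by Xist and 12 male by its Y-linked genes, so the order of these distances cannot be read as one of genotype. The chi-square over degrees of freedom, which also grows with depth, was 13.1 for cultures 10 and 11 and 3.98 for 10 and 12.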
